A study of Mus musculus with 6 samples.

How the data were processed

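Colon of 3 control mice and 3 mice with Ihh (Indian hedgehog) deleted by a Cre recombinase under the villin promoter, which is active in intestinal epithelium, had been profiled on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per mouse. Per the labels' protocols, the colon was put into Trizol at dissection, total RNA was extracted with it, and biotin-labelled target was hybridised by a standard Affymetrix procedure. The series' design text gives postnatal day 12 for the harvest, while the growth protocol in the labels gives day 9 to day 12, so the age of each mouse is not known exactly.

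The values used were the log2 expression values deposited by the authors, which per the submitters' processing notes had been made with RMA (background correction, quantile normalization and summary of the probes of a transcript); its version, and the genome build behind the probe design, are not given in the sources used here. The deposited table held 35557 rows for 6 arrays, and 0 further columns of per-sample values. Array medians lay between 7.10 and 7.14 and the arrays differed at one rank by up to 0.336 on the log2 scale, so the deposited columns were not identical in distribution over these rows. Pearson correlations between arrays, taken across rows, ranged from 0.9855 to 0.9936, and the lowest share of rows that differed between 2 arrays was 99.9%, so no array was a copy of another. Array values carry no counts, and precision is limited by the number of arrays, 3 per group.

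Rows were named through the platform's annotation of 2016. Of 35557 rows, 21789 had 1 gene symbol, 1621 had several and 12147 were unnamed here. Entrez identifiers of 21698 rows were matched to a RefSeq table on assembly GRCm38.p6, used for names and gene neighbourhood alone, and 0 symbols changed. Rows with 1 symbol entered the test. For the 999 genes with more than 1 row the row with the highest mean over the 6 arrays was kept, which left 19938 genes. Among the changed genes 35 had more than 1 row, and in 5 of these another row had the opposite sign.

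Mutant was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided, Benjamini-Hochberg adjustment over 19938 genes, adjusted p under 0.05), with the litter as a fixed block. All adjusted p values of single genes are from this limma fit unless another setting is named. The block was used because the series' design text calls the samples paired and states that the mutant and the control of one number were littermates. In the data, the deviations of littermates from their group means correlated by 0.0128, 0.00516 and 0.0613 over genes, so the pairing rests on the labels and not on the values. The fit leaves 2 residual degrees of freedom per gene, to which the shared prior adds 5.85. Errors beside a log2 change are its standard error in this fit. Each mouse is a separate animal, so a gene's residuals hold the spread of the mutant minus control difference between litters. The p values also rest on the shared prior, which outweighs those residuals (5.85 against 2 degrees of freedom).

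Before the data were examined, 45 lists of genes (pathways, cell types of the gut wall, and cell types or tissues that a colon sample could also hold) were fixed and tested with limma's camera, with the correlation between genes preset to 0.01, a minimum of 4 measured genes and adjustment over the 45 lists. They held 913 genes, of which 840 were measured. Camera with an estimated correlation, camera on ranks and fry were alternatives. The genes named were fixed by a rule at the same time. They are Ihh, Ptch1, Gli1 and Hhip; the 12 largest rises and the 12 largest falls among genes that passed and moved the same way in 3 litters, without predicted genes and olfactory or vomeronasal receptors; and up to 4 members with the smallest p in the direction of each shifted list, or up to 2 of another list. Other genes named in the text were chosen after their values were seen.

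The scripts were tested on simulated data with 200 of 19938 genes changed in the comparison of mutant with control. Variances were drawn from the prior that limma had fitted to the real arrays, with independent normal errors. The assumptions of the fit thus held by construction, and the real data may depart from them. They recovered 43.3% of genes changed by 0.5 on the log2 scale, 97% of those changed by 1 and 100% of those changed by 2. Of 169 genes called, 9 (5.3%) were unchanged ones. Of 50 simulated lists shifted by 0.3 with independent genes, camera called 50 with the preset and 45 with an estimated correlation, and of 50 unshifted ones 1 and 0.

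The alternatives were no litter block, the litter as a random block, eBayes with trend and robust, array weights, no genes of the dimmest 30%, quantile normalization, median centring, the mean of all rows of a gene, each litter left out, all rows of the table, and an ordinary paired test without the shared variance. The level of Xist as a covariate, all rows with a gene name, and all rows with the prior variance of the tested genes were added after seeing the data. Bootstrap intervals of list medians used 10000 draws of genes, so they hold no spread between mice. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.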

Results

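Gene expression was measured in whole colon of 3 control mice and 3 VilCre;Ihhflox/flox mice, in which Ihh, the gene of the secreted signal Indian hedgehog, is deleted in intestinal epithelium. Each mutant was paired with a control littermate, which gave 3 litters and 6 arrays. The comparison asked which genes differ in young colon when the epithelium lacks this ligand. Values are RMA expression on the log2 scale, and every change is mutant minus control.

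The Ihh signal itself was 8.50, 8.54 and 8.68 in controls 1 to 3 and 8.37, 8.22 and 8.22 in mutants 1 to 3. It was lower in the mutant of each litter, by a mean of -0.30 ± 0.09, and did not pass the test (adjusted p = 0.139). The Ihh value summarises probes along the whole transcript and the deleted part is not stated in the labels, so it checks the labels only in part. Several genes that respond to hedgehog signalling fell. Ptch1, the hedgehog receptor and a transcriptional target, went from 10.4 ± 0.107 to 9.0 ± 0.0629 (SD, n = 3 each), which is 2.71-fold lower in mutants, with adjusted p = 0.000493 in the limma fit. Hhip, a hedgehog-binding inhibitor that the pathway induces, fell 4.46-fold from 8.57 ± 0.342 to 6.42 ± 0.0837 (SD, n = 3 each; limma adjusted p = 0.000493). Gli1, a transcription factor of the pathway and its usual readout, fell by 0.78 ± 0.08 (adjusted p = 0.00355). Foxf2, a mesenchymal forkhead factor, fell by 1.24 ± 0.11 (adjusted p = 0.00166). Of 18 measured hedgehog ligands, receptors and targets, 6 fell, 0 rose and 12 did not pass, and 9 fell when adjusted over the list alone. The other 2 that fell, named after their values were seen, were Foxf1 (-0.74) and Foxl1 (-0.49). Shh, the other hedgehog ligand of the gut, stood at 0.01 and did not pass. Camera placed the list below other genes (adjusted p = 1.4e-09), with adjusted p = 0.313 with an estimated correlation.

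**Figure D1:**
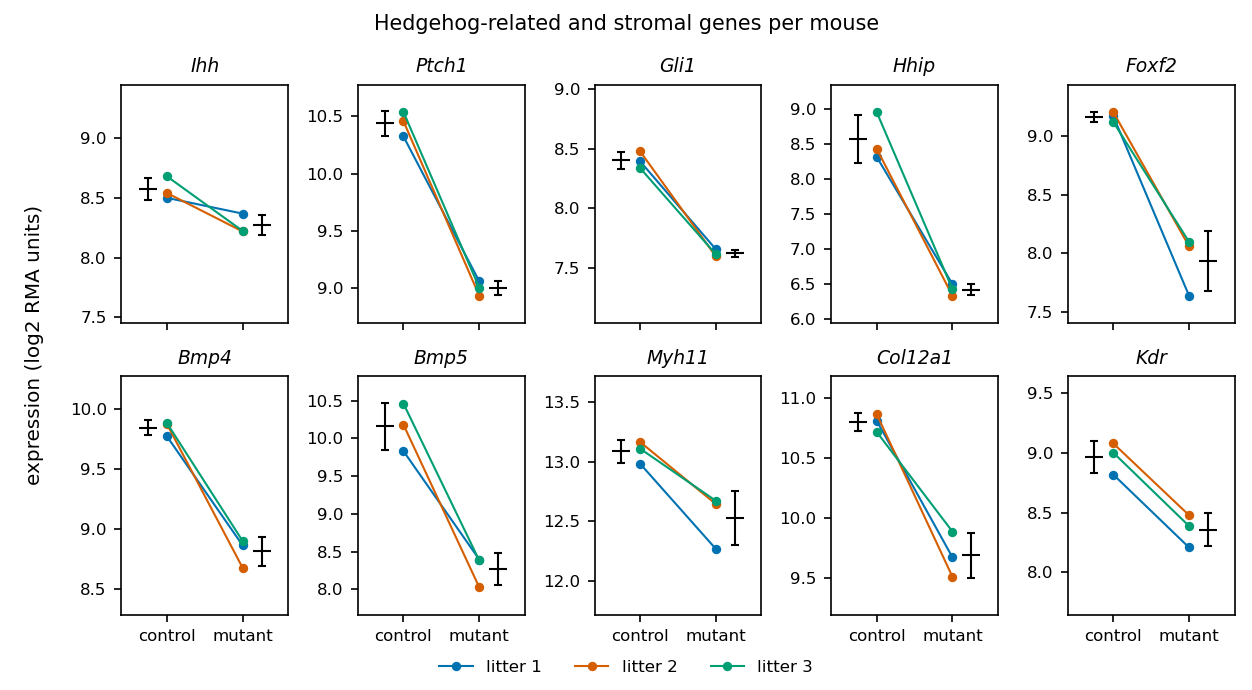
Expression in log2 RMA units of 10 hedgehog-related and stromal genes in control and mutant colon; each line joins the littermates of one litter, and the black marks give the group mean and SD (n = 3). The mutant lies below its littermate in all 3 litters for each gene drawn, with the smallest gap for Ihh (-0.30).

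Bone morphogenetic protein (BMP) ligand and target genes fell in part, and antagonists went both ways. Of 23 measured ligands, antagonists and targets, 8 fell, 2 rose and 13 did not pass, and 13 fell and 2 rose when adjusted over the list alone. The ligand genes Bmp5 and Bmp4 fell by 1.89 ± 0.14 (adjusted p = 0.000944) and by 1.04 ± 0.09 (adjusted p = 0.00159). Id4 and Smad6, which BMP signalling induces, fell by 0.72 ± 0.10 and by 0.56 ± 0.08. The 2 genes that rose, picked out after their values were seen, both encode BMP antagonists, Chrdl2 (1.5 ± 0.16) and Grem1 (0.50 ± 0.09). Camera placed the list below other genes (adjusted p = 3.5e-07), with adjusted p = 0.308 with an estimated correlation. Of 23 Wnt ligands and secreted antagonists, 3 fell and 1 rose, and 4 fell and 1 rose when adjusted over the list alone. Sfrp2, a secreted Wnt antagonist, fell by 1.03 ± 0.12 and the ligand gene Wnt5a by 0.69 ± 0.10. The 1 gene that rose, picked out after its value was seen, was another secreted antagonist, Sfrp1 (0.79 ± 0.08, adjusted p = 0.00344). The shift of this list was small (median -0.09, camera adjusted p = 0.0416, and adjusted p = 0.626 with an estimated correlation) and was lost under 10 of 15 alternatives, with camera adjusted p = 0.419 without litter 1 and 0.0560 without litter 3. In the TGF-beta and activin list 3 of 22 genes fell and 0 rose, with 5 falls and 1 rise adjusted over the list alone. Among them Ltbp4, which binds latent TGF-beta in the matrix, fell by 0.71 ± 0.12. The list had camera adjusted p = 0.0136 and adjusted p = 0.332 with an estimated correlation, and without litter 1 the camera value was 0.106.

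Many genes of contractile and stromal cells were lower in the mutant colon. Of 28 measured smooth muscle genes, 15 fell, 0 rose and 13 did not pass, and 24 fell when adjusted over the list alone. Myh11, the smooth muscle myosin heavy chain, fell by 0.56 ± 0.09 (adjusted p = 0.0166), and Cnn1, calponin, by 0.72 ± 0.12 (adjusted p = 0.0198). Cald1, caldesmon, and Flna, filamin A, fell by 0.58 ± 0.10 and by 0.54 ± 0.10. Without litter 1 the adjusted p was 0.0687 for Cnn1, 0.0513 for Cald1 and 0.0568 for Flna, and without the litter block it was 0.104 for Cald1. The median of the list was -0.46 (camera adjusted p = 1.3e-20), with adjusted p = 0.313 with an estimated correlation. It was -0.68, -0.45 and -0.28 in litters 1, 2 and 3.

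Of 19 myofibroblast and subepithelial mesenchyme genes, 9 fell, 2 rose and 8 did not pass, and 13 fell and 2 rose when adjusted over the list alone. Of these 19 genes, 11 also stand in other lists, Hhip, Bmp5 and Bmp4 among them. Ogn, the matrix proteoglycan osteoglycin, fell by 1.43 ± 0.11 (adjusted p = 0.00128). The genes that rose, picked out after their values were seen, were Dlk1 (1.31 ± 0.15) and F3, tissue factor (0.43 ± 0.09). Camera gave adjusted p = 5.3e-10, against adjusted p = 0.308 with an estimated correlation. General fibroblast genes did not pass as a list (median -0.16, camera adjusted p = 0.0831), but were called as lower under 3 of 15 alternatives (0.0374 without litter 3, 0.0224 in the eBayes fit with trend and robust, and 0.0168 with the Xist level as a covariate). Of 17 measured, 3 fell and 1 rose, and 3 fell and 2 rose when adjusted over the list alone. Mfap5, a microfibril protein, fell by 1.09 ± 0.08, while Mgp, matrix Gla protein, rose by 1.58 ± 0.17.

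Among 25 collagen genes 7 fell, 0 rose and 18 did not pass, and 11 fell when adjusted over the list alone. Col12a1 fell by 1.11 ± 0.11 (adjusted p = 0.00272), Col15a1 by 0.87 ± 0.09, and the basement membrane chains Col4a6 and Col4a5 by 0.88 ± 0.10 and by 0.68 ± 0.08. The list median was -0.30 (camera adjusted p = 1.3e-09, and adjusted p = 0.332 with an estimated correlation), and it was -0.54 in litter 1, -0.19 in litter 2 and -0.11 in litter 3. Of 34 other matrix genes 12 fell, 0 rose and 22 did not pass, and 17 fell and 1 rose when adjusted over the list alone. Efemp1, a fibulin, fell by 1.17 ± 0.12, and the laminin chains Lamb1 and Lamc1 by 0.76 ± 0.08 and by 0.64 ± 0.10. Camera gave adjusted p = 1.4e-12, against adjusted p = 0.313 with an estimated correlation. Matrix proteases and inhibitors went both ways, with 6 rises and 4 falls among 27 genes, and 8 rises and 7 falls adjusted over the list alone. Plau, urokinase, fell by 1.10 ± 0.09 and Mmp3, stromelysin 1, rose by 0.85 ± 0.09. The list as a whole was not shifted (camera adjusted p = 0.997), and its median (-0.01) and the test's direction were below 0 while its mean was 0.08.

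Blood vessel genes were lower as well. Of 20 measured blood endothelium genes 11 fell, 0 rose and 9 did not pass, and 17 fell when adjusted over the list alone. Kdr, the main receptor of vascular endothelial growth factor, fell by 0.61 ± 0.08 (adjusted p = 0.00696), and Plvap, a protein of fenestrated endothelium, by 0.63 ± 0.09 (adjusted p = 0.00947). Aplnr, the apelin receptor, and Cd93 fell by 0.63 ± 0.10 and by 0.54 ± 0.08. Without the litter block the adjusted p was 0.106 for Plvap, 0.138 for Aplnr and 0.0723 for Cd93, and without litter 3 it was 0.0520 for Aplnr and 0.0570 for Cd93. The list median was -0.42 (camera adjusted p = 3.6e-16, and adjusted p = 0.308 with an estimated correlation). Of 9 pericyte genes 2 fell, 4 adjusted over the list alone, with Rgs5 at -0.51 ± 0.08 (adjusted p = 0.0154, and 0.0610 without litter 3). Of 8 lymphatic endothelium genes 1 fell, also 1 adjusted over the list alone, with Itga9 at -0.88 ± 0.10. These lists had camera adjusted p = 0.00540 for pericytes and 0.0114 for lymphatic endothelium, and adjusted p = 0.313 and adjusted p = 0.332 with an estimated correlation. Without litter 1 the camera values were 0.0754 for pericytes and 0.262 for lymphatic endothelium.

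Genes of nerve, glia, interstitial cells and mesothelium changed in single cases. Interstitial cell of Cajal genes fell in 2 of 9 cases, with 2 falls and 1 rise adjusted over the list alone. The largest change was in Ano1, the chloride channel of these pacemaker cells, at -1.31 ± 0.13 (adjusted p = 0.00276). Of 22 enteric neuron genes 1 fell (Calb2, -0.88 ± 0.11) and 1 rose (Tac1, the substance P precursor, 0.86 ± 0.11), the same counts as adjusted over the list alone. Of 12 enteric glia genes 1 fell (Cryab, -0.61 ± 0.10), and 2 adjusted over the list alone. None of these 3 lists passed (camera adjusted p = 0.0948, 0.149 and 0.0617), but each was called as lower under some of 15 alternatives. The interstitial cell list was called under 2, with 0.0171 for the litter as a random block and 0.0234 in the eBayes fit with trend and robust. The neuron list was called under 3, with 0.00104 without litter 2, 0.0374 without litter 3 and 0.000770 with the Xist level as a covariate, and its median was -0.34, 0.09 and 0.01 in litters 1, 2 and 3. The glia list was called under 3, with 0.0277 without the litter block, 0.0358 for the litter as a random block and 0.0380 without the dimmest 30% of genes. Of 13 mesothelium genes 2 rose, 4 rises and 1 fall adjusted over the list alone. Krt18, a keratin that other epithelia share, rose by 0.60 ± 0.08. The mesothelium list had camera adjusted p = 0.00518, and adjusted p = 0.313 with an estimated correlation; without litter 2 the camera value was 0.0588.

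**Figure D2:**
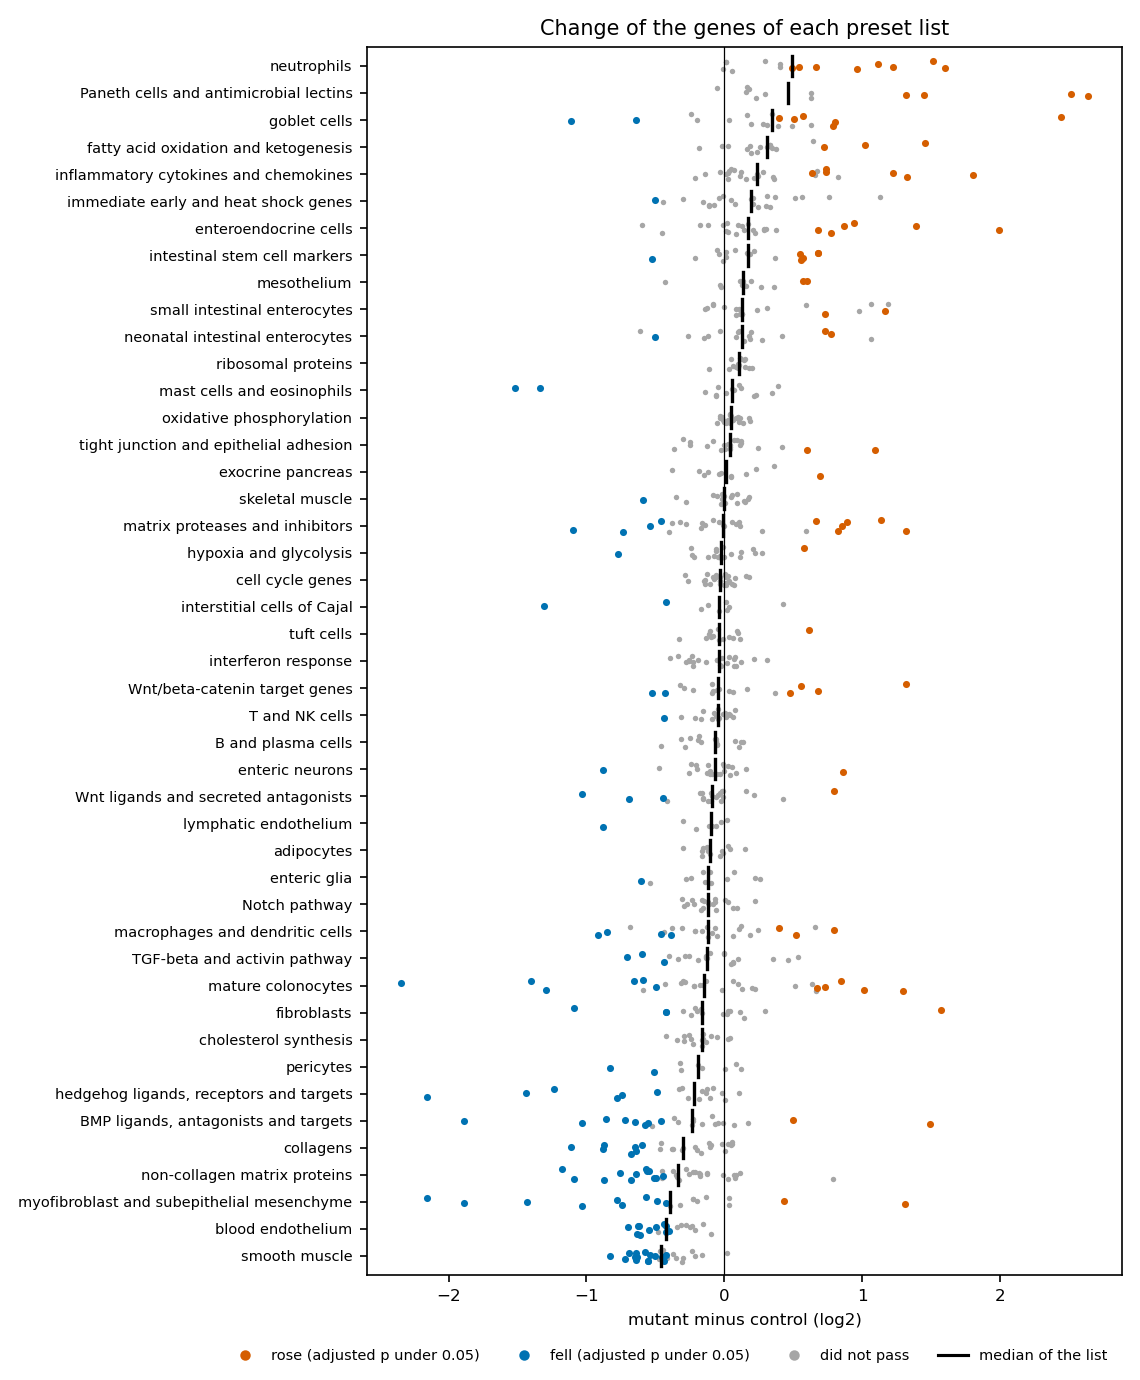
Log2 change (mutant minus control) of each measured gene of the 45 lists, 1 point per gene, with the median of the list as a black bar; orange points rose and blue points fell with a limma adjusted p under 0.05, and grey points did not pass. Smooth muscle (median -0.46) and blood endothelium (median -0.42) lie at the bottom and neutrophil genes (median 0.49) at the top.

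Some hormone, mucus and antimicrobial genes of the epithelium rose. Small intestinal tissue or a different stretch of gut in the mutant samples could not be told apart from other causes (see the closing section). This also limits the reading of epithelial genes that vary along the gut. Of 25 enteroendocrine genes 6 rose, 0 fell and 19 did not pass, and 10 rose and 2 fell when adjusted over the list alone. Gcg, the proglucagon gene, rose 3.98-fold, from 10.2 ± 0.0483 to 12.2 ± 0.310 (SD, n = 3 each; limma adjusted p = 0.000459). Cck, cholecystokinin, rose by 1.39 ± 0.08 (adjusted p = 0.000493) and the prohormone convertase gene Pcsk1 by 0.77 ± 0.08. Nts, neurotensin, rose by 0.87 ± 0.12, with adjusted p = 0.00910 and 0.0838 without the litter block. Camera gave the list adjusted p = 4.1e-06, against adjusted p = 0.313 with an estimated correlation.

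Of 19 goblet cell genes 6 rose, 2 fell and 11 did not pass, and 12 rose and 3 fell when adjusted over the list alone. Retnlb, a secreted bactericidal protein of goblet cells, rose 5.44-fold (adjusted p = 0.00910, but 0.169 in the eBayes fit with trend and robust). Spdef, a transcription factor of goblet cells, rose by 0.80 ± 0.09 and Spink4 by 0.79 ± 0.08. The 2 that fell, picked out after their values were seen, were the mucus proteins Clca1 (-1.11 ± 0.15) and Zg16 (-0.64 ± 0.12). Camera gave adjusted p = 1.2e-05, against adjusted p = 0.313 with an estimated correlation. Of 12 Paneth cell and antimicrobial lectin genes 4 rose and 0 fell, and 6 rose when adjusted over the list alone. They were the lectins Reg3b (2.64 ± 0.16), Reg3g (2.51 ± 0.24) and Reg4 (1.45 ± 0.12) and the protease Mmp7 (1.32 ± 0.19). Lyz1, the Paneth cell lysozyme, stood at -0.05 ± 0.10 and did not pass. Reg3g had adjusted p = 0.00233, and 0.0839 without the litter block. Camera gave the list adjusted p = 2.3e-08, against adjusted p = 0.308 with an estimated correlation.

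Of 18 intestinal stem cell markers 5 rose, 1 fell and 12 did not pass, and 6 rose and 1 fell when adjusted over the list alone. Lgr5, a receptor of crypt base stem cells, rose by 0.68 ± 0.10 (adjusted p = 0.0140), and Slc12a2, an ion cotransporter of the crypt, by 0.68 ± 0.09. Sox9 and Smoc2 rose by 0.55 ± 0.08 and by 0.57 ± 0.10, with adjusted p = 0.0845 for Sox9 without the litter block and 0.0918 for Smoc2 without litter 3. Ascl2, a transcription factor of the same stem cells, named after its value was seen, fell by 0.53 ± 0.10 (adjusted p = 0.0286). The list had camera adjusted p = 0.00187, and adjusted p = 0.313 with an estimated correlation. Wnt/beta-catenin target genes were not shifted (18 genes, 4 rises, 2 falls, camera adjusted p = 0.701), with 5 rises and 3 falls adjusted over the list alone, a median of -0.04 and a mean of 0.08. Of 29 cell cycle genes 0 rose and 0 fell, also adjusted over the list alone (limma; camera adjusted p = 0.407, but 0.0215, as lower, without litter 2).

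Genes of mature colonocytes went both ways, with 5 rises and 6 falls among 30, and 8 rises and 11 falls adjusted over the list alone. Slc9a3, the apical sodium-hydrogen exchanger, rose by 1.30 ± 0.11 (adjusted p = 0.00131). Car4, a carbonic anhydrase of surface colonocytes, fell by 1.40 ± 0.18 (adjusted p = 0.00768). Saa1, an acute phase apolipoprotein, fell 5.07-fold (adjusted p = 6.3e-05); it has a near-identical paralog in Saa2, so the gene behind this value is uncertain. The list did not pass (camera adjusted p = 0.163), but was called as lower in the eBayes fit with trend and robust (0.0115). Of 22 tight junction and adhesion genes 2 rose, the claudin genes Cldn2 (1.09 ± 0.08) and Cldn4 (0.60 ± 0.08), with 3 rises and 1 fall adjusted over the list alone and no shift of the list (camera adjusted p = 0.308). Of 17 fatty acid oxidation and ketogenesis genes 3 rose and 0 fell, and 9 rose when adjusted over the list alone. Pdk4, which restrains glucose oxidation, rose by 1.45 ± 0.12 and Angptl4 by 1.02 ± 0.10. Camera gave this list adjusted p = 6.2e-08, against adjusted p = 0.332 with an estimated correlation. Its median was 0.36, 0.06 and 0.44 in litters 1, 2 and 3, beside 0.56, -0.08 and 0.17 for small intestinal enterocyte genes.

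Several neutrophil and inflammatory genes rose. Of 15 neutrophil genes 8 rose, 0 fell and 7 did not pass, and 10 rose when adjusted over the list alone. Cxcr2, a chemokine receptor of neutrophils, had a measured mean of 4.18 ± 0.262 in controls and 5.79 ± 0.479 in mutants (SD, n = 3 each) and rose with limma adjusted p = 0.000493. The calprotectin genes S100a8 and S100a9 rose by 1.52 ± 0.23 and by 0.96 ± 0.12, and Lcn2, lipocalin 2, which epithelium can also make, rose by 1.22 ± 0.14. Cxcr2, S100a8, the chemokine gene Cxcl5, the mast cell genes Mcpt1 and Mcpt2 and the protease gene Mmp3 were among the dimmest 30% of genes, and no background level was used, so the sizes of their changes are uncertain. The list had camera adjusted p = 2.5e-10, and adjusted p = 0.313 with an estimated correlation. Of 27 inflammatory cytokine and chemokine genes 6 rose, 0 fell and 21 did not pass, and 11 rose when adjusted over the list alone. Il1b rose by 1.81 ± 0.12 (adjusted p = 0.000664), the neutrophil chemoattractant Cxcl5 by 1.33 ± 0.13 and Duoxa2, a maturation factor of an epithelial oxidase, by 0.73 ± 0.09. Camera gave adjusted p = 2.4e-08, against adjusted p = 0.313 with an estimated correlation. Macrophage and dendritic cell genes went both ways (3 rises and 4 falls among 25, and 4 rises and 8 falls adjusted over the list alone; camera adjusted p = 0.0948). In the mast cell and eosinophil list the mucosal mast cell proteases Mcpt1 and Mcpt2, which are close paralogs, fell by 1.52 ± 0.28 and by 1.34 ± 0.12. The list held 2 falls among 15 genes, and 2 rises and 2 falls adjusted over the list alone, and was not shifted (camera adjusted p = 0.779, test direction up, median 0.05, mean -0.11). Mcpt1 had adjusted p = 0.0274, and 0.181 in the eBayes fit with trend and robust. B and plasma cell genes and interferon response genes did not pass in any case (0 of 16 and 0 of 24 in the limma fit, also adjusted over the list alone; camera adjusted p = 0.104 and 0.236). As lists, however, B and plasma cell genes were called as lower without litter 1 (0.0219), without litter 2 (0.0394) and with array weights (0.0332), and interferon response genes as lower without litter 3 (3.9e-06).

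**Figure D3:**
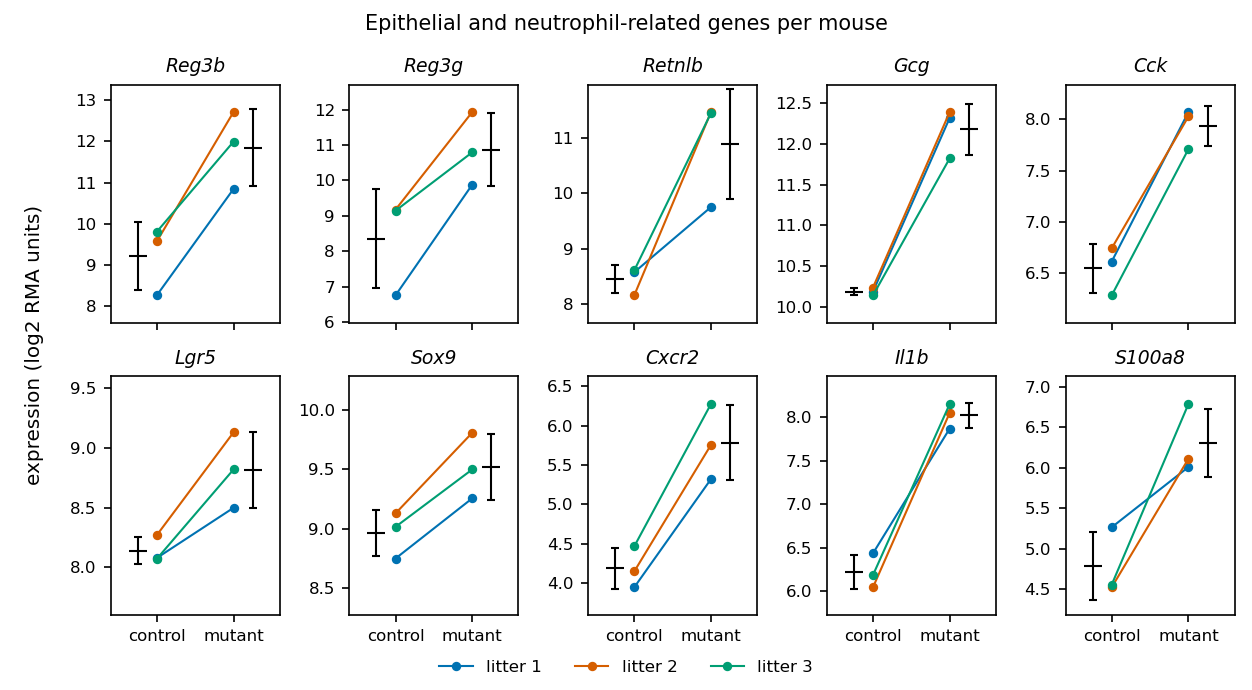
Expression in log2 RMA units of 10 epithelial and neutrophil-related genes in control and mutant colon; each line joins the littermates of one litter, and the black marks give the group mean and SD (n = 3). The mutant lies above its littermate in all 3 litters for each gene drawn, by 1.99 for Gcg and 0.68 for Lgr5 on average.

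Among the other lists that camera called, none had more than 2 members that passed. Small intestinal enterocyte genes rose in 2 of 19 cases and in 6 adjusted over the list alone (camera adjusted p = 0.00326, 0.275 without litter 1, and adjusted p = 0.332 with an estimated correlation). Slc10a2, the apical bile acid transporter of ileum, rose by 1.17 ± 0.16. The list median was 0.56 in litter 1, -0.08 in litter 2 and 0.17 in litter 3. Notch pathway genes (median -0.12, camera adjusted p = 0.00605), cholesterol synthesis genes (-0.16, 0.00299) and ribosomal protein genes (0.10, 0.0119) held 0 members that passed in the limma fit, also adjusted over the list alone. With an estimated correlation these lists had adjusted p = 0.332, adjusted p = 0.613 and adjusted p = 0.332, and without litter 2 the camera values were 0.0588, 0.957 and 0.0946. Exocrine pancreas genes, which would mark another organ in the sample, did not pass as a list (camera adjusted p = 0.510), with 1 of 12 risen, also 1 adjusted over the list alone. The litters differed, with medians of 0.19, -0.45 and 0.24 in litters 1, 2 and 3, and without litter 2 the list was called as higher (7.4e-05). The tuft cell, T and NK cell, adipocyte, neonatal enterocyte, oxidative phosphorylation, skeletal muscle, hypoxia and immediate early gene lists did not pass either (camera adjusted p from 0.0818 to 0.779). They held at most 3 members that passed, and at most 7 adjusted over the list alone. Immediate early and heat shock genes, with medians of -0.14, 0.03 and 0.48 in litters 1, 2 and 3, were called as higher without litter 1 (0.00381), without litter 2 (0.0215) and with array weights (0.0169). Neonatal enterocyte genes were called as higher without litter 2 (0.0422) and without litter 3 (0.0464). In the tuft cell list the median was -0.04, the mean 0.01 and the test direction down.

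Over all 19938 genes, 751 changed, 330 upward and 421 downward, and all 751 moved the same way in the 3 litters, as did 35.9% of all genes tested. At least 2-fold rises were seen in 55 genes and falls in 48. The largest rises were Reg3b (6.22-fold), Reg3g (5.71-fold), Retnlb (5.44-fold), Ceacam10 (5.34-fold), Cd177 (5.29-fold) and Gcg (3.98-fold). Next came Fgf15, the bile acid-induced hormone (3.54-fold), Il1b (3.5-fold), the pantetheinase gene Vnn1 (3.38-fold) and the dim Cxcr2 (3.03-fold as measured). Fkbp5, a glucocorticoid-induced chaperone (3.02-fold), and Mgp (2.98-fold) followed. Cd177 is known from neutrophils, but its control mean was 8.74, against 4.18 for Cxcr2 and 4.78 for S100a8. The cells behind its rise are therefore uncertain. The largest falls were Saa1 (5.07-fold), Hhip (4.46-fold), Bmp5 (3.71-fold), the transglutaminase gene Tgm3 (3.62-fold), Col6a4 (3.25-fold), Mcpt1 (2.86-fold), Cpxm2 (2.72-fold), Ptch1 (2.71-fold), Nmu, neuromedin U (2.70-fold), Ogn (2.69-fold), Car4 (2.64-fold) and Slc3a1, an amino acid transporter subunit (2.6-fold). With trend and robust in eBayes, Fgf15 had adjusted p = 0.102 and Tgm3 adjusted p = 0.0993. The count of 751 rests on the variance that limma shares between genes. An ordinary paired test without it gave 0 genes, with 1969 at an unadjusted p under 0.05, and a limma fit on all 35557 rows gave 2, with 3761 at an unadjusted p under 0.05. Camera called 23 of 45 lists with its preset correlation (10 up, 13 down), and 0 with an estimated correlation. The estimate was 0.42 for smooth muscle, but 0.0123 for blood endothelium and -0.042 for the BMP and stem cell lists, against the preset 0.01. A higher correlation between genes thus does not account for the lost calls of these last 3 lists. With an estimated correlation camera takes its degrees of freedom from the residuals (2 here), and with the preset from the number of genes. Blood endothelium, at nearly the same correlation, had camera adjusted p = 0.308 against 3.6e-16. For such lists a call lost with an estimated correlation is therefore not evidence of correlated genes. The other splits of the 6 arrays that part all 3 pairs of littermates, as the real one does, called 17, 14 and 7 lists with the preset. Such splits still hold part of the difference between mutant and control, so these are not counts expected by chance. Fry called 4 (blood endothelium, myofibroblast, BMP and stem cell lists).

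The sex of the mice is not given in the labels. Xist, the transcript of X inactivation, was at 11.96, 5.96 and 5.83 in controls 1 to 3 and at 6.41, 12.03 and 11.92 in mutants 1 to 3, and the Y-linked Uty ran the other way (4.30, 9.57 and 9.39 in controls, 9.72, 4.20 and 4.21 in mutants). Littermates thus differed in these transcripts in every litter, in one sense in litter 1 and in the opposite sense in litters 2 and 3. By these transcripts control 1 and mutants 2 and 3 were female, and the other mice male. No litter was matched for sex, and the groups were not balanced, so a gene's mean change can hold part of a sex effect. With the Xist level as a covariate, chosen after seeing the data, 1230 genes changed, 738 of the 751 among them. This fit leaves fewer residual degrees of freedom than the 2 of the main fit, beside 5.11 from the shared prior. Its counts thus rest largely on that prior.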

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

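The test of the array rows that carry several gene symbols was chosen after seeing that these rows lay outside the comparison of single genes. In a limma fit of their own, 30 of 1621 such rows changed between mutant and control (18 higher, 12 lower; 140 at an unadjusted p under 0.05), with log2 changes from -1.10 to 2.19. No gene is named from them. The 12147 rows without a gene name here gave 0 in their own limma fit, with 728 at an unadjusted p under 0.05.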

How the results depend on the processing

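The 751 changes kept their sign under each alternative that tested them, which was largely fixed in advance. Each moved the same way in 3 litters, so leaving out 1 litter could not turn it. The fits without the block, with a random block, and with trend and robust leave the log2 change itself unaltered. Counts of changed genes were within 1.5 times of 751 for no replicate block (638, of which 575 shared), the litter as a random block (803), eBayes with trend and robust (878), quantile normalization (746), median centring (754), the mean of rows (720) and no genes of the dimmest 30% (860). Leaving out 1 litter gave 546 to 798 genes changed (247 to 403 raised, 299 to 484 lowered), 20 to 26 lists and -0.39 to -0.23 for Ihh. Of the 751 genes, 557, 575 and 452 were called again without litters 1, 2 and 3. The shared prior then had 5.12, 18.3 and 11.6 degrees of freedom, against 5.85 in the main fit, so these totals also rest on the prior. Of the 140 named genes, 14 lost their call without the block, and 9, 8 and 16 without litters 1, 2 and 3. None reversed, which these settings could not produce for genes that moved the same way in 3 litters. Without litter 2 the share of rises among calls was 50.5%, against 43.9%.

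Array weights gave 1246 genes (512 raised, 734 lowered) and Ihh at -0.35 with adjusted p = 0.0418, the one setting in which Ihh passed (0.0695 to 0.623 in the others); the cause was not tested. The Xist level as a covariate, chosen after seeing the data, gave 1230 genes (558 raised, 672 lowered); the cause was not tested. All rows of the table gave 2 (1 raised, 1 lowered), because the 12147 unnamed rows are noisier (median residual SD 0.159 against 0.0987) and the shared prior fell to 3.01 degrees of freedom from 5.85. With the prior variance of the tested genes the same rows gave 1004, with 668 of the 751 among them. That prior understates the spread of the unnamed rows, which gave 0 in their own limma fit, so 1004 can be too high. Without it, 132 rows passed at an adjusted p under 0.10. The ordinary paired test without eBayes gave 0 changed genes (0 raised, 0 lowered) with 2 residual degrees of freedom per gene. It differs from the main fit only in leaving out the variance shared between genes. Camera on ranks called 23 lists, fry 4, and camera with an estimated correlation 0, with 5 at an unadjusted p under 0.05. Signal over background was not given, so dim genes were judged by their mean alone.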

Other observations

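Tests of the sex of the mice, of the outer gut wall, of the share of epithelium, and of small intestinal tissue were chosen or changed after their results were seen, as were the place of Fabp2 among the enterocyte genes and the look at Apoa4, Fabp1 and the Hox13 genes alone; the lists of Hox, imprinted and glucocorticoid-induced genes were written down before theirs. Many genes that lie beside Dlk1 also rose in the mutant colon. Of 48 measured genes between Dlk1 and Dio3, an imprinted region with many microRNA genes, 21 rose, 0 fell and 27 did not pass, with a median change of 0.42. Dlk1 rose by 1.31 ± 0.15, Meg3 by 0.98 ± 0.08 and Rian by 1.02, whereas Rtl1 (-0.06) and Dio3 (0.03) did not pass. Of 40 microRNA genes of this region 16 rose, 10 of them among the dimmest 30% of genes (Mir379 and Mir381, for example). With no background level the sizes of these changes are uncertain, as is the median of 0.42, to which 28 dim genes contribute. The 20 brighter genes of the region had a median of 0.39, and 10 of them rose. Total RNA was measured, so a microRNA gene's value may come from a longer transcript that spans it. The genes of the region may therefore not be separate observations, and mature microRNAs were not measured as such.

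H2-Ab1 and Cd74, of the class II pathway, fell by 0.92 ± 0.17 and by 0.85 ± 0.17, H2-Aa stood at -0.68 ± 0.21 without passing, and Ccr2, a monocyte chemokine receptor, rose by 0.80 ± 0.15. Aqp8, a water channel of colonocytes, fell by 1.29 ± 0.18. These genes were picked after their values were seen.

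The rise between Dlk1 and Dio3 could reflect the sex of the mice or delayed maturation. Sex would turn the direction between litter 1 and the others, but the lowest of the 3 litter medians, dim genes included, was 0.40, which argues against it. Imprinted and fetal growth genes outside the region had a median of -0.0254 (95% bootstrap interval -0.16 to 0.29), with Hmga2 up and Mest down, so delayed maturation cannot be told apart because these genes go both ways. A response of the mesenchyme to the loss of Ihh stays open and untested.

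Of 5 measured ileal bile acid genes 3 rose in the colon (Fgf15, Slc10a2 and Slc51b), with a median of 1.16, and Slc51a and Fabp6 did not pass. Small intestinal tissue in the mutant samples cannot be told apart: the 17 other enterocyte genes had a median of 0.12 over the litters, but 0.56, -0.15 and 0.15 in litters 1, 2 and 3, against 0.71, 1.20 and 1.31 for the bile acid genes. Apoa4 differed by 2.27 in litter 1 and Fabp1 by 2.61, -2.18 and 2.50. For Apoa4 and Fabp1, litters 1 and 3 thus hold values that such tissue would give and litter 2 does not. In litter 2, however, Fgf15 differed by 2.806 and Fabp6 by 2.398, the largest of the 3 litters for each. These bile acid genes, picked after their values were seen, leave ileal tissue in litter 2 open. A different stretch of gut cannot be told apart either: 10 posterior Hox genes had a median of -0.0908 (interval -0.25 to 0.02), above the bound of -0.29, but that median dilutes the most posterior ones. Hoxa13, Hoxb13 and Hoxd13 had a median of -0.59 in litter 2 and -0.47 in litter 3, where the bile acid genes differed most, and 0.32 in litter 1; an effect of the genotype stays open as well.

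The fall of smooth muscle, endothelial and matrix genes (45 of 107 fell, median -0.42) could come from less outer gut wall, more epithelium or sex. Nerve, glia, interstitial and mesothelial genes had a median of -0.0274 (interval -0.10 to 0.03) against -0.46 for smooth muscle. Without mesothelial genes, some of which are epithelial keratins, it was -0.09 (-0.12 to -0.00457; -0.23 in litter 1 against -0.68), and -0.10 (-0.16 to -0.03) over the 32 brighter ones of the whole set, which argues against less outer wall as the whole cause and leaves a smaller part open. More epithelium would lower all other cells alike, but 130 genes of nerve, glia, interstitial cells, leukocytes other than neutrophils, and adipocytes had a median of -0.0616 (interval -0.10 to -0.04), and the 52 brighter ones -0.12 (interval -0.17 to -0.05), which argues against it as the whole cause and leaves a smaller part open. The 130 genes include those of leukocytes, whose own share may differ, whereas the nerve, glia and interstitial cell genes taken alone do not. Of 15 general epithelial genes 1 rose and 0 fell, with a median of 0.04 (interval -0.03 to 0.14). These intervals draw genes and hold no spread between mice. In litters 1, 2 and 3 the 52 brighter genes had medians of -0.16, -0.04 and -0.09, against -0.49, -0.35 and -0.26 for the set that fell. Nerve, glia and interstitial cell genes had -0.23, 0.02 and -0.03, against -0.68, -0.45 and -0.28 for smooth muscle. With the Xist level as a covariate the median was -0.43, which argues against sex; an effect of the genotype stays open and was not tested, and scan batches are not given.

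Fkbp5, Pdk4 and Hif3a rose, and a hypothesis is a glucocorticoid response. Other glucocorticoid-induced genes had a median of 0.16 (interval -0.13 to 0.44), with Per1, Zbtb16, Sgk1 and Cebpd up and Mt2 down, so this cannot be told apart from other causes.

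There are 10 splits of the 6 arrays, too few for a share under 0.05. All but the real one keep part of the difference between mutant and control in their contrast and their residual spread. Their counts are therefore not counts expected by chance. The real split changed 751 genes and the highest other 3, so 1 split gave as many; that other split, of control 1 with mutants 2 and 3, follows the Xist level. For lists, the real split called 23 and the highest other 23, and 3 splits gave as many; those that match it part 1 pair of littermates each, and the other splits that part all 3 pairs of littermates called 17, 14 and 7 lists.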
